A study of Homo sapiens with 18 samples.

How the data were processed

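Ribosome footprints and mRNA were measured in HEK293 cells, a human embryonic kidney line, and in 2 clonal lines derived from it with Cas9: UFM1-KO, which lacks the ubiquitin-like modifier UFM1, and UFSP2-KO, which lacks the protease that takes UFM1 off its targets. Per the labels' protocols, the cytosolic fraction was the digitonin lysate and the membrane fraction was the Triton lysate of the pellet that digitonin left behind. Footprints were made with RNase I from each fraction, per the labels' protocols, and mRNA libraries were made from total RNA of whole cells with a stranded kit after removal of ribosomal RNA, per the same protocols. There were 12 ribosome profiling libraries and 6 mRNA libraries in 9 groups, with 2 libraries per group that the labels mark a and b. Each knockout was represented by 1 line described as clonal, so the effect of a knockout cannot be separated from other differences between clones. The labels do not say that replicates came from separate cultures, and no p-value below measures spread beyond these libraries.

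Each deposited table held raw counts, given as whole numbers per versioned Ensembl transcript, with a length for each transcript. Reads were aligned to GRCh38 with TopHat2 2.1.1, per the submitters' processing notes. The program that counted the reads, its settings and the annotation release are not given in the sources used here. The tables had no headers, and their values showed that no normalization had been applied to the deposited counts: library totals differed between replicates. The second column is a length, the same in every library of an assay and 1 larger in the mRNA tables, and was read as coding length in codons after a fixed trim at the ends. There were 26679 transcripts for each footprint library and 98334 for each mRNA library, of which 43611 had no length and 0 counts.

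Groups of entries often carried identical counts, as arises when a read shared by several isoforms is counted for each of them. Entries with identical counts in every library of an assay were therefore merged into 1 distinct transcript feature, named by its first transcript. The 21223 footprint entries with a count in any library became 14377 distinct features. For mRNA, the 25605 transcripts matched between the assays by ID and length were used, and those with a count became 15431 distinct features. Isoforms that share most of their reads remained separate features, so counts of features are not counts of genes, and transcripts of near-identical gene copies cannot be told apart at this level. The plan had assumed genes as the unit. No table at hand paired these transcript IDs with gene names, so the gene lists fixed before the data were examined were not tested, the transcripts of UFM1, UFSP2 and RPL26 were not looked up, and the knockouts were not checked in the counts.

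Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 after filterByExpr with a minimum count of 10 and TMM normalization. Models had 1 coefficient per group: 1 model over the 12 footprint libraries, 1 over the 6 mRNA libraries and 1 over all 18 libraries for features present in both assays. They tested 11065 footprint features, 13889 mRNA features and 12619 features in the joint model. Features were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison, two-sided. The comparisons were membrane against cytosol in each line, the change of that ratio between lines, knockout against WT in each fraction, knockout against WT and knockout against knockout in mRNA, and the footprint change less the mRNA change. Standard errors (SE) of log2 changes were derived from the F statistic. CPM denotes counts scaled to library size, with TMM factors, in the usual unit of edgeR.

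The test, the samples and the normalization of these comparisons were chosen before the data were examined. The membrane class was defined afterwards as a replacement for the gene lists: features with an edgeR adjusted p under 0.05 and over 2-fold more normalised footprints in the membrane fraction than in the cytosol. In a comparison of footprints of a knockout with WT, the class was taken from the membrane-to-cytosol ratio of the other knockout's libraries. The filter, the normalization and the spread behind its adjusted p came from the model over all 12 footprint libraries, those compared included. For mRNA the WT class was used. Its shift, the median log2 change of the class less that of the remaining features, was tested with camera of limma 3.58.1, two-sided, with a preset correlation of 0.01 and again with an estimated correlation, and p-values were adjusted over 13 comparisons. Under other scalings, classes or blocks and with a library left out, a shift was judged as called or not on the camera p before this adjustment, at 0.05. Camera compares features of the class with other features. With the preset correlation its p does not measure the spread of the class shift between libraries. Shares of counts in the class common to the 3 lines were compared with exact permutation tests, for which 2 libraries against 2 cannot give a two-sided p under 0.333.

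The rule for naming, set before the data were examined, took the 8 largest changes in each direction of each comparison among called features with a mean of at least 10 CPM and no overlap between the libraries compared. For mRNA, 35 features that rose and 110 that fell in UFM1-KO met these conditions, and 289 and 354 did in UFSP2-KO. Because IDs without gene names say little, the names were limited afterwards to 4 of the features that met them: the largest rise and the largest fall in mRNA over both knockouts, and the single feature called in each test of a knockout's membrane enrichment against WT.

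Both knockouts were compared with the same WT libraries, which alone makes their changes correlate. This was sized with 50 simulations in which all 6 mRNA libraries, WT included, were drawn at the mean WT levels with the fitted spreads. The WT libraries are too few to be split. The tests were run on simulated counts with the spreads of these libraries and means fitted with no difference in the comparison tested. In these, 100 features were then changed by 2-fold and 100 by 4-fold. For membrane against cytosol this setting is unlike the data, where 37.5% of features were called in WT. Recovery there need not hold for the real test. For membrane against cytosol in WT, 37% of the 2-fold and 87% of the 4-fold changes were recovered. For the change of membrane enrichment in UFM1-KO the recovery was 11% and 57%, and for UFM1-KO mRNA 38% and 89%. For UFM1-KO footprints beyond mRNA in the membrane fraction it was 5% and 69%. A simulated class shift of 0.5 in UFM1-KO cytosol was returned as 0.43 with a camera p of 3.8e-12 by limma, and 3.08e-06 with an estimated correlation. Features were drawn independently of each other, so the simulation did not test the preset correlation. In the real comparison the estimated correlation was 0.0986, against the preset 0.01.

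Library totals ranged from 1393032 to 11388755 footprint counts and from 37451244 to 68675420 mRNA counts over all entries. Because shared reads are repeated, totals over distinct features are lower, from 919295 to 7657808 footprints and from 13556380 to 25014521 mRNA counts. Replicates spread beyond counting error: the chi-square of their counts per degree of freedom was 3.26 to 4.9 for footprints and 34.8 to 43 for mRNA. Counting error was thus a small part of the spread in mRNA and a larger one in footprints. The value pools all features, and counting error weighs more in those with few counts. Intervals on shares are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. Alternatives were RLE size factors, library size alone, no filter, the Wald test of DESeq2 1.42.0, models of only the groups compared, the letter as a block, each library left out in turn, and other ways to merge transcripts. Where a left-out library leaves 1 in its group, that library is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.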

Results

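Ribosome footprints were sequenced from membrane and cytosolic fractions, and mRNA from whole cells, of 3 HEK293 lines: unedited cells (WT) and the clonal knockouts UFM1-KO and UFSP2-KO. UFM1 is a ubiquitin-like protein that is attached to other proteins, among them RPL26, a protein of the large ribosomal subunit, and UFSP2 is a protease that removes it. Each of the 9 groups held 2 libraries, a and b. In the membrane fraction, libraries a and b held 3893984 and 11388755 footprint counts in WT, 8748060 and 2848544 in UFM1-KO, and 2874937 and 4232842 in UFSP2-KO. In the cytosol they held 1393032 and 6666021 in WT, 1907000 and 2671157 in UFM1-KO, and 1587853 and 5383754 in UFSP2-KO. The mRNA libraries held 51760318 and 58264307 counts in WT, 68675420 and 51111414 in UFM1-KO, and 64540404 and 37451244 in UFSP2-KO. Log2 CPM (normalised counts) of the libraries of a group correlated with Pearson's r of 0.957 to 0.98 for footprints and 0.973 to 0.976 for mRNA, across transcript features, which are not independent replicates. The SD of the log2 difference between replicates was highest in the cytosol, at 0.68 to 0.72, against 0.4 to 0.51 in the membrane fraction. A feature here is a set of transcripts with identical counts, and the tables do not pair transcript IDs with gene names.

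Footprints in the membrane fraction against the cytosol show which transcripts had more footprints in the Triton lysate of the digitonin pellet. Below, "at the membrane" means in this fraction. Without gene names, the fractions were not checked with known membrane or cytosolic genes. In WT cells the features fell into a large group near equal levels and a smaller group far higher at the membrane. This smaller group, called the membrane class, had an edgeR adjusted p under 0.05 and an enrichment over 2-fold, and held 2535 of 11065 features in WT, 2402 in UFM1-KO and 2502 in UFSP2-KO. The median enrichment of the class was 43.7-fold in WT, 39.1-fold in UFM1-KO and 37.3-fold in UFSP2-KO (n = 2 libraries per fraction). The same 2269 features were in the class of all 3 lines, and 212 were in the class of 1 line only. These 2269 features held on average 1.02% of WT cytosol footprints, so their ratios rest on low cytosol counts. Of the WT class, 92.4% was also in the class of UFM1-KO and 94.2% in that of UFSP2-KO. Features over 2-fold lower at the membrane numbered 547 in WT, 253 in UFM1-KO and 699 in UFSP2-KO.

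By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2802 features were higher and 1351 lower at the membrane in WT. In UFM1-KO the test called 2545 higher and 650 lower, and in UFSP2-KO 2741 higher and 1345 lower. Over the 7797 features with a mean of at least 10 CPM, the log2 enrichment of WT correlated with that of UFM1-KO at Pearson's r = 0.959 and with that of UFSP2-KO at 0.96, across features. The share of calls that were higher depended on the scaling: it was 67.5% in WT, 79.7% in UFM1-KO and 67.1% in UFSP2-KO with TMM, and 56.5%, 55.2% and 54.8% with library size only, which moved the median log2 ratio of all features by -0.14, -0.29 and -0.19.

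**Figure D1:**
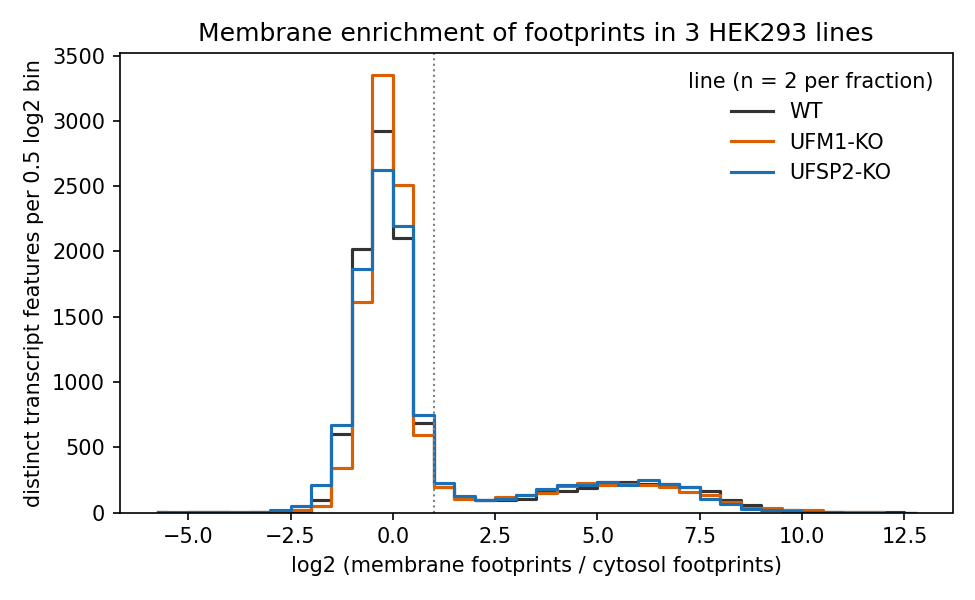
Number of distinct transcript features (vertical axis) per 0.5-wide bin of log2 membrane over cytosol footprints (horizontal axis) in WT, UFM1-KO and UFSP2-KO, with 2 libraries per fraction. The dotted line marks 2-fold; the membrane class to its right held 2535, 2402 and 2502 features.

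The change of the membrane-to-cytosol ratio between lines addresses whether loss of UFM1 or of UFSP2 moved translation between the fractions. Few single features were called as changed. In simulations this test recovered 11% of 2-fold and 57% of 4-fold changes in UFM1-KO, and 12% and 58% in UFSP2-KO. Smaller changes could thus have been missed. Transcript ENST00000301244.10 was strongly enriched at the membrane in WT (log2 7.44, SE 0.38) and less so in UFSP2-KO (log2 2.24, SE 0.51). Its membrane footprints were 816 and 780 CPM in WT, 15.9 and 13.1 CPM in UFSP2-KO, and 1870 and 1670 CPM in UFM1-KO. Its cytosol counts were only 5 to 14 in every library, and its mRNA fell as well, from 129 and 123 CPM in WT to 6.81 and 7.71 CPM in UFSP2-KO. The log2 mRNA change was -4.12 (SE 0.26, edgeR adjusted p = 5.78e-08), and in UFM1-KO the mRNA rose by 1.52 (SE 0.22, edgeR adjusted p = 0.00126), to 291 and 429 CPM. Transcript ENST00000369886.6 was lower at the membrane than in the cytosol in WT (log2 -6.42, SE 0.59), and in UFM1-KO the log2 ratio was -1.03 (SE 0.47). Its footprints were 1.23 and 0.698 CPM at the membrane and 62 and 85 CPM in the cytosol of WT, and 16.4 and 1.07 CPM at the membrane and 28.1 and 18.2 CPM in the cytosol of UFM1-KO.

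The edgeR test of the change called 1 feature in UFM1-KO, ENST00000369886.6 (log2 change 5.39, SE 0.81, adjusted p = 0.00546), and 1 in UFSP2-KO, ENST00000301244.10 (log2 change -5.2, SE 0.8, adjusted p = 0.00791). Between the knockouts it called 4 features, 3 with a higher ratio in UFM1-KO, and both of these transcripts were among them (edgeR adjusted p = 0.0265 and 0.00198). At an unadjusted edgeR p under 0.05 there were 539, 487 and 742 features, or 4.87%, 4.4% and 6.71% of those tested. With no change at all, a share of 0.05 would fall under this threshold. DESeq2 called 0 features in UFM1-KO (244 unadjusted), 2 in UFSP2-KO (221 unadjusted) and 4 between the knockouts (375 unadjusted). With library size only, edgeR called 4 features in UFM1-KO, of which 25% had a higher ratio, against 100% of the 1 call with TMM, and the median of all features moved by -0.14. The change of ENST00000369886.6 rested on membrane library a of UFM1-KO, with 89 counts against 2 in library b: without it the log2 change was 2.07 and not called, nor was it called without WT membrane library b (4.85). The call of ENST00000301244.10 ended without UFSP2-KO cytosol library a (-4.19) or without WT cytosol library b (-4.22). The count for UFM1-KO was 11 without its cytosol library b and 5 without WT cytosol library a, of which 1 had a higher ratio in either case, and that for UFSP2-KO was 4 and 9.

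As a group, the membrane class held a larger share of membrane footprints in the knockout libraries than in the WT libraries. In the membrane fraction its share of footprints was 25.1% ± 0.57 (SD, n = 2) in WT, 27.4% ± 0.35 in UFM1-KO and 29% ± 0.78 in UFSP2-KO, and every knockout library lay above both WT libraries. In the cytosol the shares were 1.02% ± 0.27, 1.23% ± 0.21 and 1.16% ± 0.28, and libraries of different lines overlapped, while for each letter both knockouts lay above WT (1.38% and 1.36% against 1.21% in libraries a, 1.09% and 0.966% against 0.833% in libraries b). In mRNA they were 12.4% ± 0.57, 12.4% ± 0.35 and 12.3% ± 0.42. The two-sided exact permutation p against WT was 0.333 in the membrane fraction of either knockout, the smallest that 2 libraries against 2 can give, 0.667 in the cytosol and 1 in mRNA. Chance alone leaves 33.3% of such splits without overlap. Counting error was small beside these differences: the exact 95% binomial interval of UFSP2-KO membrane library a, for example, was 28.4% to 28.6%.

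**Figure D2:**
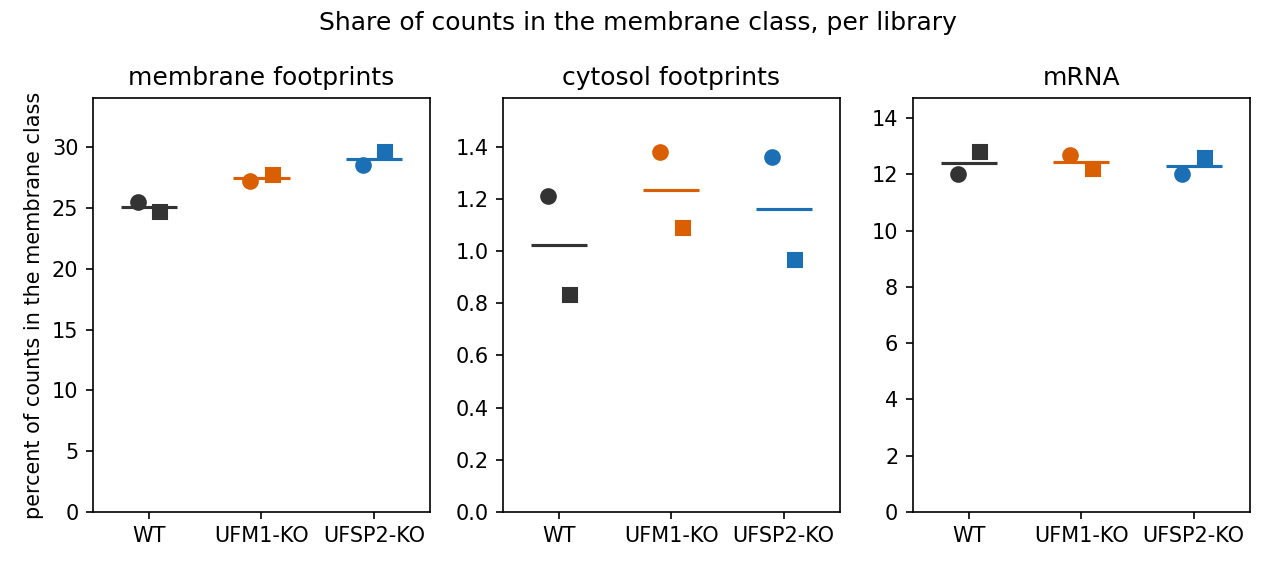
Percent of each library's counts in the membrane class common to the 3 lines, for membrane footprints, cytosol footprints and mRNA; circles are library a, squares library b, bars the mean. In the membrane fraction the shares were 24.7% to 25.5% in WT and 27.2% to 29.6% in the knockouts.

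Relative to other features, the log2 enrichment of the class shifted by a median of -0.33 in UFM1-KO less WT and -0.23 in UFSP2-KO less WT. The adjusted p with limma's camera and a preset correlation was 1.3e-04 and 0.0472. With an estimated correlation it was 0.5 and 0.745, and neither call held. The class held few counts in the cytosol, and the sign of its shift depended on the cytosol libraries included. Without WT cytosol library b the shifts were 0.048 and 0.14, and without the knockout's own cytosol library a they were 0.0046 and 0.07. The UFSP2-KO call also ended without UFSP2-KO membrane library a (-0.2) or WT membrane library a (-0.18), and with RLE size factors or library size only (-0.23 for both).

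Footprints of each fraction were next compared between each knockout and WT. More features were called in UFSP2-KO than in UFM1-KO in both fractions, a difference in number that was not tested. In the membrane fraction of UFSP2-KO 580 features rose and 652 fell, and in its cytosol 165 rose and 277 fell. In UFM1-KO 57 rose and 82 fell in the membrane fraction, and 18 rose and 76 fell in the cytosol. In UFSP2-KO all 270 features called in both fractions changed in the same direction, and the changes correlated at r = 0.546 across 7797 features. In UFM1-KO 17 of 18 did, with r = 0.286. The membrane class rose relative to other features in UFSP2-KO membrane footprints, by a median log2 of 0.23, and 298 of its 2402 members were called higher and 140 lower. The adjusted p of this shift was 1.4e-04 with limma's camera and a preset correlation, and 0.5 with an estimated correlation.

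These calls come from edgeR with adjusted p under 0.05. They were sensitive to single libraries: without any 1 of the 4 libraries compared, the membrane count fell by over 1.5 times in either knockout, to 14 to 28 in UFM1-KO and to as few as 407 in UFSP2-KO. Without UFM1-KO cytosol library a or b the UFM1-KO cytosol count was 15 or 29, without WT cytosol library b it was 9, and the UFSP2-KO count was 274, 245 and 170 without the corresponding libraries. The share of cytosol calls that were higher was 79.3% in UFM1-KO and 61.2% in UFSP2-KO without the knockout's cytosol library b, and without UFM1-KO membrane library b 53.6% of the UFM1-KO membrane calls were higher. Models of only the groups compared called 466 features in UFM1-KO and 2123 in UFSP2-KO in the membrane fraction, and 8 and 294 in the cytosol. DESeq2 called 45 and 528 in the membrane fraction, and 47 and 249 in the cytosol. With library size only, which moved the median of all features by 0.145, the cytosol calls of UFM1-KO numbered 50 and 46% were higher, against 19.1% with TMM; with RLE size factors 47.8% of the UFSP2-KO cytosol calls were higher, against 37.3%. In UFM1-KO membrane footprints the class shift was 0.062 (limma camera adjusted p = 0.194), and it was 0.1 without WT membrane library a. In the cytosol the class lay higher by 0.31 in UFM1-KO and 0.34 in UFSP2-KO (adjusted p = 2.7e-04 and 2.4e-04 with camera of limma, 0.5 for both with an estimated correlation), but -0.037 and -0.0225 without WT cytosol library b, and 0.0185 and 0.072 without the knockout's cytosol library a. The UFM1-KO call also ended with library size only (0.33). The class held few cytosol counts: 914 features with log2 enrichment of 5 to 7 in UFSP2-KO summed to 2080 and 862.5 CPM in the WT libraries. At this enrichment the median and the summed change were 0.454 and 0.15 in UFM1-KO, and 0.585 and 0.478 in UFSP2-KO. Over log2 7 they were 0.222 and 0.02 in UFM1-KO, and 0.293 and 0.459 in UFSP2-KO.

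Messenger RNA levels were compared to find transcripts altered in each knockout line and those that separate the lines. UFSP2-KO differed from WT in 999 of 13889 features, of which 332 rose and 667 fell. UFM1-KO differed in 274, of which 53 rose and 221 fell. The knockouts differed from each other in 2217 features, 1102 higher in UFM1-KO and 1115 higher in UFSP2-KO. Among the features that met the rule for naming, the largest rise was that of ENST00000311208.11, from 1.75 and 0.445 CPM in WT to 216 and 150 CPM in UFSP2-KO (log2 7.41, SE 0.44, edgeR adjusted p = 3.77e-08). Its footprints rose in the membrane fraction (log2 3.32, SE 0.35, edgeR adjusted p = 1.88e-07) and in the cytosol (log2 3.86, SE 0.44, edgeR adjusted p = 2.45e-06). The largest fall was that of ENST00000361566.6, from 50.8 and 63.5 CPM in WT to 5 counts and 1 count in the UFSP2-KO libraries (fitted log2 -8.34, SE 0.4, edgeR adjusted p = 1.97e-09), while in UFM1-KO it rose by 1.06 (SE 0.24, edgeR adjusted p = 0.0273). Its membrane footprints were 131 and 146 CPM in WT and 1 count and 0 counts in UFSP2-KO.

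Few features changed alike in both knockouts: 0 were called higher in both and 20 lower in both by edgeR, and 49 were called in opposite directions. Independent lists of these sizes would share 1.27 and 10.6 in the same direction, and the number for opposite directions was not computed. Log2 changes correlated at r = 0.053 across features, and 57.2% had the same sign. Unchanged knockouts were simulated against shared WT libraries, which were simulated too. They gave r = 0.495 (0.478 to 0.521 in 50 simulations), a share of 66.6%, 0 shared calls and 0 calls in opposite directions. The covariance was 0.042 against 0.075 simulated (0.0716 to 0.0801), a difference of -0.033. Across all features the knockouts were therefore less alike than unchanged knockouts were in simulations with shared WT libraries. The observed WT libraries themselves were not held fixed in these simulations. The WT libraries cannot be split, so part of the likeness in the 20 shared calls can come from them.

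The counts of mRNA calls depended on single libraries. Without WT library b edgeR called 59 features in UFM1-KO and 194 in UFSP2-KO, 0 in the same direction in both, and r was 0.387; without WT library a it called 125 and 598, with r = 0.197. Without UFM1-KO library a or b the UFM1-KO count was 151 or 598, with 73 shared calls in the latter case, and without UFSP2-KO library b the UFSP2-KO count was 568. Without UFSP2-KO library a the knockouts shared 53 calls in the same direction. The difference between the knockouts was steadier, with 1371 calls without UFM1-KO library a and 1564 to 1966 without any 1 of the other libraries. With library size only, 15.4% of the UFSP2-KO calls were higher, against 33.2% with TMM, and the median of all features moved by -0.14. With each library's trend over coding length removed, 53.1% of 1246 UFSP2-KO calls were higher. In UFM1-KO, DESeq2 called 547 features and a model of only the groups compared 581.

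**Figure D3:**
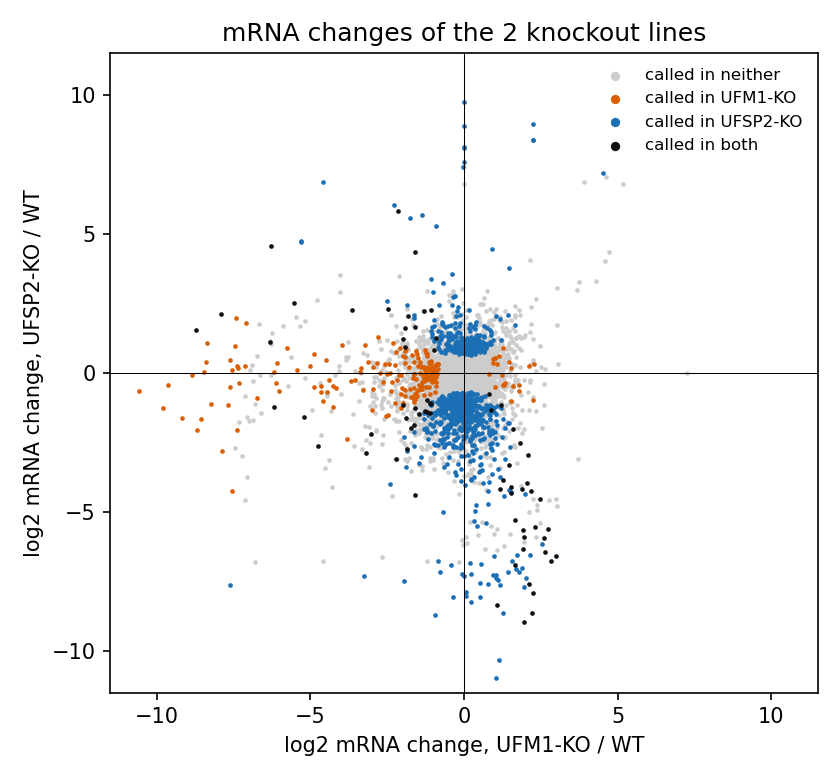
Log2 mRNA change of each feature in UFM1-KO against WT (horizontal axis) and UFSP2-KO against WT (vertical axis), 2 libraries per line, coloured by where edgeR called it. Of the features called in both knockouts, 20 lie in the lower left quadrant and 49 in the quadrants of opposite sign.

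Footprint changes were then set against mRNA changes, to see whether translation changed beyond the mRNA level. Where mRNA changed, footprints mostly followed. Among the 7635 features tested in both assays with a mean of at least 10 CPM in footprints, 541 were called in UFSP2-KO mRNA and 110 in UFM1-KO mRNA. Of the 541, 518 (95.7%) had membrane footprints that differed in the same direction and 466 (86.1%) cytosol footprints; in UFM1-KO it was 108 (98.2%) and 99 (90%) of 110. Of those called in footprints too, 284 and 136 in UFSP2-KO and 38 and 20 in UFM1-KO, 0 changed in the opposite direction. Across the 7635 features, log2 changes of membrane footprints and mRNA correlated at r = 0.693 in UFSP2-KO and 0.534 in UFM1-KO, and those of cytosol footprints and mRNA at 0.455 and 0.242.

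The joint edgeR model called few features whose footprints changed by another amount than their mRNA. It called 10 in the membrane fraction of UFSP2-KO, 6 higher and 4 lower, and 2 higher in its cytosol. Among the 10 was ENST00000311208.11, whose footprints rose less than its mRNA (log2 difference -4.11, SE 0.59, edgeR adjusted p = 5.71e-04). In UFM1-KO edgeR called 0 in either fraction. At an unadjusted p under 0.05 there were 540 features (4.28%) in the membrane fraction and 752 (5.96%) in the cytosol. A share of 0.05 would fall there with no change at all. DESeq2 called 2 and 0 in UFM1-KO, with 483 and 706 unadjusted, and 21 and 12 in UFSP2-KO. Without a filter on low counts edgeR called 5 and 24 in UFM1-KO and 33 and 17 in UFSP2-KO. Simulated 2-fold differences of this kind were recovered in 2% to 8% of cases and 4-fold ones in 44% to 69%, so only large differences were detectable. Against mRNA the membrane class lay higher in UFSP2-KO membrane footprints by 0.26 (limma camera adjusted p = 7.49e-06, 0.5 with an estimated correlation) and in UFM1-KO by 0.093 (adjusted p = 0.0369, 0.652 with an estimated correlation). In cytosol footprints it lay higher by 0.41 and 0.48 in UFM1-KO and UFSP2-KO (limma camera adjusted p = 1.0e-04 for both, 0.5 with an estimated correlation), and by 0.07 and 0.092 without WT cytosol library b; the UFM1-KO shift was 0.1 without UFM1-KO cytosol library a, and its call ended with library size only (0.41). In mRNA itself the class shifted by -0.044 in UFM1-KO and -0.014 in UFSP2-KO (limma camera adjusted p = 0.553 and 0.676).

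The count of 10 in UFSP2-KO fell to 2 without WT membrane library b, to 5 or 6 without WT membrane library a, WT mRNA library b, or UFSP2-KO membrane library a or b, and rose to 34 without WT mRNA library a. In its cytosol the count of 2 rose to 16 without WT mRNA library a, 12 without UFSP2-KO cytosol library b, 8 without WT cytosol library a and 6 without UFSP2-KO mRNA library b. With RLE size factors 85.7% of the UFSP2-KO membrane calls were higher and with library size only 75%, against 60% with TMM. For UFM1-KO the count of 0 became 9 in the membrane fraction without UFM1-KO mRNA library b and 1 without WT mRNA library a, and 15, 8 and 5 in the cytosol without UFM1-KO cytosol library b, WT cytosol library a or UFM1-KO mRNA library b. The cytosol class shift of UFSP2-KO also lost its call without UFSP2-KO cytosol library a (0.16), and the membrane shift of UFM1-KO without UFM1-KO membrane library b (0.089), WT membrane library b (0.05), UFM1-KO mRNA library a (0.057) or WT mRNA library b (0.047).

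Membrane enrichment varied with coding length outside the membrane class. Among the 8374 features in the class of no line, the median log2 enrichment in WT was -0.74 for coding lengths up to 100 codons and 0.39 over 1600 codons. In UFSP2-KO it was -1.0 and 0.36, and in UFM1-KO -0.4 and 0.17. Spearman's rho of enrichment with length was 0.535 in WT, 0.562 in UFSP2-KO and 0.353 in UFM1-KO, across features. In the 2269 features of the class common to the 3 lines, rho was 0.023, -0.0098 and -0.049, but the WT median rose from 2.78 up to 100 codons to 5.94 over 400 and up to 800 codons and was 4.59 over 1600 codons. The cytosol libraries of WT differed in this trend: with membrane library b, rho was 0.297 for cytosol library a and 0.559 for b. The highest value of a UFM1-KO pair was 0.351, so UFM1-KO and WT overlapped, and the lowest of a UFSP2-KO pair was 0.415, above every UFM1-KO pair.

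**Figure D4:**
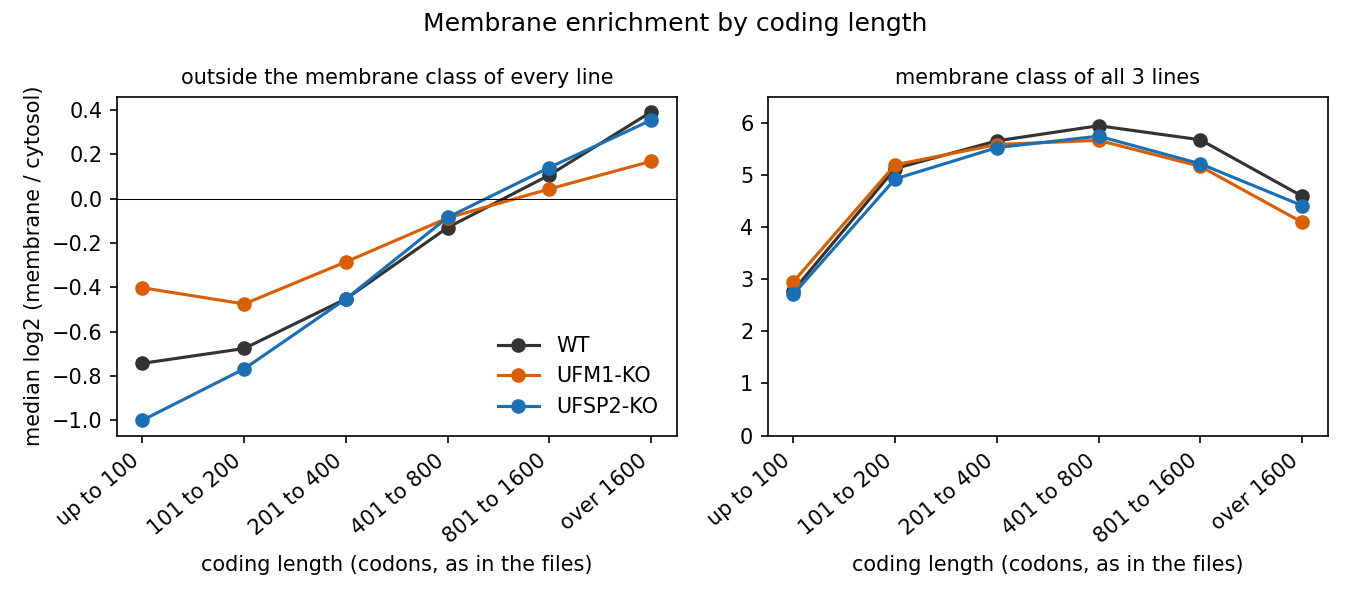
Median log2 membrane over cytosol footprints (vertical axes) by coding length in codons (horizontal axis), for features in the membrane class of no line (left) and of all 3 lines (right); each point is the median of a length bin, with 2 libraries per fraction. On the left the medians of WT run from -0.74 to 0.39 and those of UFM1-KO from -0.4 to 0.17.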

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

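The following 4 counts are numbers of features called in tests of a difference between cell lines. Of the tests weighed here, that of how the class was chosen and that of the spread between cytosol libraries were chosen after the result was seen. The edgeR test of the change in the membrane-to-cytosol ratio called 1 feature in UFM1-KO against WT, and it called 1 feature in UFSP2-KO against WT. Between UFM1-KO and UFSP2-KO the same test called 4 features, 3 with a higher ratio in UFM1-KO and 1 with a lower one. With 1 library left out, the first count ranged from 0 (without UFM1-KO membrane library a or WT membrane library b) to 11 (without UFM1-KO cytosol library b), and the second from 0 (without UFSP2-KO cytosol library a or WT cytosol library b) to 9 (without WT cytosol library a). The third was 13 without UFM1-KO cytosol library b, 23.1% of them higher in UFM1-KO against 75%, 1 without UFM1-KO membrane library a or UFSP2-KO membrane library b, and 0 without UFSP2-KO cytosol library a. The edgeR test of mRNA called 2217 of 13889 features between UFM1-KO and UFSP2-KO, with 1371 without UFM1-KO library a and up to 1966 without others.

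The mRNA difference between the knockouts was weighed against technical explanations. Removing each library's trend over coding length left 2502 calls, 2143 of them among the 2217, which argues against a length bias between libraries as the whole cause. Log2 differences from 1 library of each knockout correlated across features with those from the remaining libraries at r = 0.561 when the letters were kept together and at 0.896 when they were crossed, which argues against a single aberrant library. Repeated counting of 1 gene stays open, since merging features that differed by less than sampling noise took 13889 features only to 13794 (15.9% called, against 16%) and so tested little. The knocked-out gene and other differences between the clones stay open as explanations and may both contribute, since the design has 1 clone per knockout.

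Membrane-class footprints lay higher in the cytosol libraries of both knockouts, by a median log2 of 0.314 in UFM1-KO and 0.343 in UFSP2-KO relative to other features. The class was taken from the ratio of the line in neither arm, which argues against a class selected on noise in the ratios compared. Its adjusted p still shared the filter, scaling and spread of the model over all footprint libraries. Neither shift was called with an estimated correlation (limma camera adjusted p = 0.5 for both). Carried-over membrane ribosomes stay open: taking a share of each line's own membrane profile out of its cytosol libraries moved the log2 ratio to WT of the summed signal at log2 enrichment of 1 to 5 only from 0.183 to 0.19 in UFM1-KO and from 0.147 to 0.134 in UFSP2-KO, and so tested little. The more enriched features were not tested this way; before subtraction their summed ratios were 0.15 and 0.478 at log2 5 to 7, and 0.02 and 0.459 over log2 7, with UFM1-KO library a below WT library a in both bins. The spread between replicate cytosol libraries stays open. Without WT cytosol library b the shifts were -0.0366 and -0.0225, but that leaves the letters unbalanced between the lines. With the letter as a block they were 0.305 and 0.344. Each group holds 1 library of each letter, so the block could hardly move these shifts and decides nothing here. An effect of the knockouts may also be present, and 2 libraries per group do not separate it from these.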

How the results depend on the processing

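Alternatives on how transcripts were merged, on length, on the membrane class, on the overlap of the knockouts' mRNA changes and on crossed letters, and library size only for footprints beyond mRNA, were chosen after seeing the data, and the others before. The membrane class kept within 1.5 times its size under every alternative tried, and so did the calls of membrane over cytosol; the class shift of UFSP2-KO membrane footprints kept its call, alone (0.18 to 0.27) and beyond mRNA (0.2 to 0.29), without any 1 library, but not with an estimated correlation (adjusted p = 0.5 for both with limma's camera). Where a value moved, the cause was not tested. Gene list tests under an estimated correlation or other scalings were not run, because the files give no gene names for the transcripts, nor were other pseudocounts, because the files hold counts. The smallest library, of WT cytosol, held 919295 counts over distinct features; whether depth limited its calls was not tested.

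With library size only, the change of enrichment in UFM1-KO had 4 calls and UFM1-KO cytosol footprints 50. Without a filter, the change of enrichment had 7 calls in UFM1-KO and 7 in UFSP2-KO, footprints beyond mRNA had 5 and 33 in the membrane fraction and 24 and 17 in the cytosol, and the knockouts' mRNA changes correlated at 0.235. DESeq2 gave 0 and 2 calls for enrichment, 45 and 528 for membrane footprints, 47 and 249 for cytosol footprints, 547 for UFM1-KO mRNA, 2 and 21 for membrane footprints beyond mRNA, and 12 for UFSP2-KO cytosol footprints beyond mRNA. Models of only the groups compared gave 466 and 2123 for membrane footprints, 8 and 294 for cytosol footprints and 581 for UFM1-KO mRNA. Without merging identical entries, UFM1-KO membrane footprints had 238 calls. With all mRNA entries that have a length, there were 618, 2139 and 4904 mRNA calls in UFM1-KO, UFSP2-KO and between them, and 42 calls shared in direction.

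With an estimated correlation, the 9 class shifts called with a preset one were not called: -0.33 and -0.23 for enrichment, 0.31 and 0.34 for cytosol footprints, 0.23 for UFSP2-KO membrane footprints, 0.41 and 0.48 for cytosol footprints beyond mRNA, and 0.093 and 0.26 for membrane footprints beyond mRNA. The enrichment shift of UFSP2-KO also lost its call with RLE size factors (-0.23) and library size only (-0.23), and with library size only so did UFM1-KO cytosol footprints (0.33) and the same beyond mRNA (0.41). With a class over 8-fold the UFSP2-KO mRNA shift, not called, was 0.0044. With the class taken from WT, its shares in UFM1-KO, UFSP2-KO and WT were 28.8%, 30.4% and 26.5% of membrane footprints, 2.13%, 1.91% and 1.65% of cytosol footprints, and 13.8%, 13.6% and 13.8% of mRNA.

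Deviations from group means of same-letter libraries correlated at 0.14 to 0.22 between cytosol groups, 0.091 to 0.12 between membrane groups, 0.032 to 0.14 between the fractions of a line and -0.36 to 0.051 between mRNA groups. This hints at a weak shared effect of the letter in footprints, and with 2 letters it does not establish pairing. The value largest in size was -0.36, between UFM1-KO and UFSP2-KO mRNA. Libraries of opposite letters thus tended to deviate alike in the mRNA of these lines, and the cause was not tested. A replicate block gave 2 calls for enrichment in UFSP2-KO, 291 for UFM1-KO membrane footprints, 246 and 852 for cytosol footprints, and a UFSP2-KO enrichment shift of -0.22 that was no longer called; it moved no other count by over 1.5 times and no other call. With crossed letters as the block, mRNA had 2197 calls in UFSP2-KO and 3556 between the knockouts, against 999 and 2217 without a block.

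Leaving out 1 library gave 0 to 11 calls for enrichment in UFM1-KO, 0 to 9 in UFSP2-KO and 0 to 13 between them; 14 to 28 and 407 to 5.6e+02 for membrane footprints; 9 to 110 and 170 to 449 for cytosol footprints; 59 to 598, 194 to 1366 and 1371 to 1966 for mRNA; 0 to 9 and 2 to 34 for membrane footprints beyond mRNA and 0 to 15 and 2 to 16 for cytosol footprints beyond mRNA. Class shifts ranged from -0.58 to 0.048 and -0.55 to 0.14 for enrichment, from -0.037 to 0.501 and -0.0225 to 0.72 in the cytosol, from 0.012 to 0.103 in UFM1-KO membrane footprints, from 0.0698 to 0.69 and 0.092 to 0.86 in cytosol footprints beyond mRNA, from 0.047 to 0.13 in UFM1-KO membrane footprints beyond mRNA, and from -0.0702 to 0.0087 and -0.044 to 0.023 in mRNA. Shared mRNA calls ranged from 0 to 73 and the correlation from 0.072 to 0.387.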

Other observations

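Of the tests in this part, those of the length trend within the membrane class and of its overlap between UFM1-KO and UFSP2-KO were chosen after the result was seen. Coding length also went with the changes of the knockouts outside the class. In UFSP2-KO the median log2 mRNA change against WT was 0.25 for features of up to 100 codons and -0.2 for those over 1600 codons, with Spearman's rho of -0.187 across 8325 features. The footprint changes themselves ran from -0.4 to 0.17 in the membrane fraction (rho = 0.193) and from -0.027 to 0.125 in the cytosol (rho = 0.102). Footprint less mRNA changes, into which the mRNA trend enters with the opposite sign by construction, ran from -0.63 to 0.29 (rho = 0.386) and from -0.26 to 0.39 (rho = 0.307). The mRNA libraries of 1 group differed in this respect too: the slope of log2 CPM per doubling of length was -0.019 in WT library a and 0.087 in b, and -0.075 and -0.019 in UFSP2-KO. In UFM1-KO the mRNA medians were 0.12 and -0.034 (rho = -0.062), those of cytosol footprints -0.102 and 0.228 (rho = 0.192) and those of membrane footprints 0.17 and -0.0099 (rho = -0.098). For footprint less mRNA changes, rho was 0.237 in the cytosol and -0.0305 in the membrane fraction.

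The length trend of membrane enrichment was smaller in UFM1-KO (rho = 0.353) than in WT (0.535) and UFSP2-KO (0.562) among features outside the membrane class. Free polysomes that sediment with membranes by weight stay open as a cause of the trend: in the class rho was 0.0231 in WT, -0.0492 in UFM1-KO and -0.00982 in UFSP2-KO, but its WT medians over length bins spanned 3.16, against 1.14 outside it. The spread between libraries may account for the difference from WT: pairs of 1 membrane and 1 cytosol library gave up to 0.351 in UFM1-KO and down to 0.297 in WT. With the same letter in both fractions UFM1-KO lay below WT, at 0.254 against 0.348 for a and 0.351 against 0.559 for b. With membrane library b and cytosol library a it lay above, at 0.312 against 0.297. The lowest UFSP2-KO pair was 0.415, so these lines did not overlap, by a gap smaller than the range of the UFSP2-KO pairs (0.415 to 0.561). An effect of UFM1 loss stays open and was not tested apart from these.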
